A study of Mus musculus with 17 samples.

How the data were processed

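RNA was sequenced in bulk from 17 samples of mice, which the labels place in 7 groups. Per the labels, the 8 intestinal samples came from the small intestine of wild-type mice, as IEC or crypts after sham operation or hepatectomy, with 2 replicates per group. The other 9 samples are labelled liver with DSS at day 0, 10 or 20, with 3 replicates per day. RNA was extracted with the RNeasy mini plus kit per the labels, and 1 ug of total RNA went into standard Illumina library preparation.

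Per the submitters' processing notes, reads were processed with STAR and Partek against mm10, with no versions given. The deposited intestinal files hold expected counts, that is estimated counts per gene symbol of which 36.7% are not whole numbers, for 33840 genes with coordinates. The deposited files labelled liver hold whole counts per numeric gene identifier for 24594 identifiers, and the counting program for them is not given in the sources used here. The expected counts were rounded to whole numbers, and values above 1e+06 are deposited with 3 digits only. Of the identifiers, 24570 (99.9%) were matched to gene symbols, and the 24 unmatched ones hold 3.93 to 22.1% of the counts of a library. Of the 33840 symbols, 32788 are in GENCODE vM21, of which 99.1% have the same start and end. Coordinates are 1-based positions on mm10. The strand used for counting is not stated, so genes that overlap another annotated gene (59 of the 185 looked up) have uncertain counts.

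Each tissue was fitted on its own in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, a quasi-likelihood F test and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. This left 18207 intestinal genes and 16694 genes in the libraries labelled liver. There were 7 comparisons: hepatectomy against sham in crypts and in IEC, the difference of those effects, crypts against IEC in sham, and the 3 pairs of days. Gene lists (46, written from general knowledge before the data were examined) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 when at least 5 members were tested, which gave 31 lists in the intestine and 34 in the libraries labelled liver. Labels, groups, comparisons, lists, alternatives and the rule for naming genes were also fixed before the data were examined. Serpinf1 was compared between days with an exact two-sided permutation test as well.

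Genes were named by rule. In crypts, in IEC, and for day 10 and day 20 against day 0 these are the 6 PEDF genes, the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the samples of the groups (leaving out predicted gene models, mitochondrial genes, immunoglobulin and T cell receptor segments and pseudogenes), and up to 4 members with the smallest p per described list, with 6 for stem cell, Wnt, S phase and mitosis lists in crypts and for PPAR-alpha and acute phase lists in the libraries labelled liver. In the other 3 comparisons 4 rises, 4 falls and up to 2 members per list are named. Lists are described when their set test passes, up to the 12 smallest p-values, together with fixed lists of epithelial cell types, proliferation, Wnt, PPAR-alpha, acute phase and other cell types. A few lists with larger p-values are given besides, and not every gene the rule selects is printed. Genes with 0 counts in a group are given as bounds against a floor of 3 counts per library.

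Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter (at least 1 CPM in every sample of a group and a mean of at least 5 CPM), a block for the replicate number, a fit of only the groups compared, a log2 fold change of at least 1, and leaving out each library. Where that leaves 1 library in a group, the pooled spread is used and the lone library is assumed to vary like the other groups. For lists they were an estimated correlation, fry, the block and RLE. Fits of the groups compared without replicate 3 of day 10, lists with a library left out, and intestinal lists in the libraries labelled liver were added after the data were seen.

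The procedure was tested on simulated data with 200 changed genes. In the layout of the crypt comparison, 73.1% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes were called, all in the right direction, and 24 unchanged genes made up 11.9% of calls, more than the nominal 0.05 share. In the layout of day 10 against day 0, 2.99%, 61.2% and 92.4% were called, and 6 unchanged genes made up 5.45% of calls. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. No sample was left out of the fits.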

Results

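Gene counts from bulk RNA sequencing were examined in 17 mouse libraries that fall into 7 groups. Per the labels, 8 libraries came from the small intestine of wild-type mice after hepatectomy, the surgical removal of liver tissue, or after a sham operation. Each was prepared either from intestinal epithelial cells (IEC), the absorptive and secretory lining of the gut, or from crypts, the epithelial pits that hold the stem cells, with 2 libraries per group. The other 9 libraries carry a liver label with DSS at day 0, day 10 or day 20, with 3 libraries per day. The series title names PEDF, a secreted protein encoded by Serpinf1, as a link between the liver and the fitness of intestinal stem cells. Total counts ranged from 26609786 to 43580050 in the intestinal libraries and from 12742629 to 42669857 in the libraries labelled liver. Unless stated otherwise, expression is given as TMM-normalised CPM (counts per 1e+06, mean ± SD over the libraries of a group), changes as log2 fold change ± SE, and adjusted p-values come from edgeR's quasi-likelihood test. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

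The libraries labelled liver were first compared with tissue markers, taken from the fixed lists after their values were seen and expressed as CPM of all counts. Alb, the main plasma protein made by hepatocytes, reached 36600 ± 1600 CPM (SD, n = 3) in the libraries labelled liver day 20. It stood at 422 ± 98 CPM in those labelled day 0 and 966 ± 810 CPM in those labelled day 10, and at 0.221 CPM or less in each intestinal group. Olfm4, a marker of crypt stem cells, showed the opposite order, with 8270 ± 300 CPM at day 0, 5180 ± 2600 CPM at day 10 and 31.8 ± 7.7 CPM at day 20, against 2080 ± 45 CPM in sham crypts. Lyz1, the lysozyme of Paneth cells, followed Olfm4, with 9410 ± 1000, 4940 ± 3300 and 39 ± 6.6 CPM at day 0, 10 and 20. Across 13894 genes, which are not independent replicates, each of the 6 libraries labelled day 0 or day 10 had a Spearman correlation of 0.896 to 0.932 with the mean of the sham crypts and of 0.661 to 0.699 with the mean of day 20. The content of the libraries labelled liver day 0 and day 10 therefore goes against their tissue label, and they are referred to only by label below. The hepatectomy and sham labels could not be checked in this way, since no gene was targeted.

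**Figure D1:**
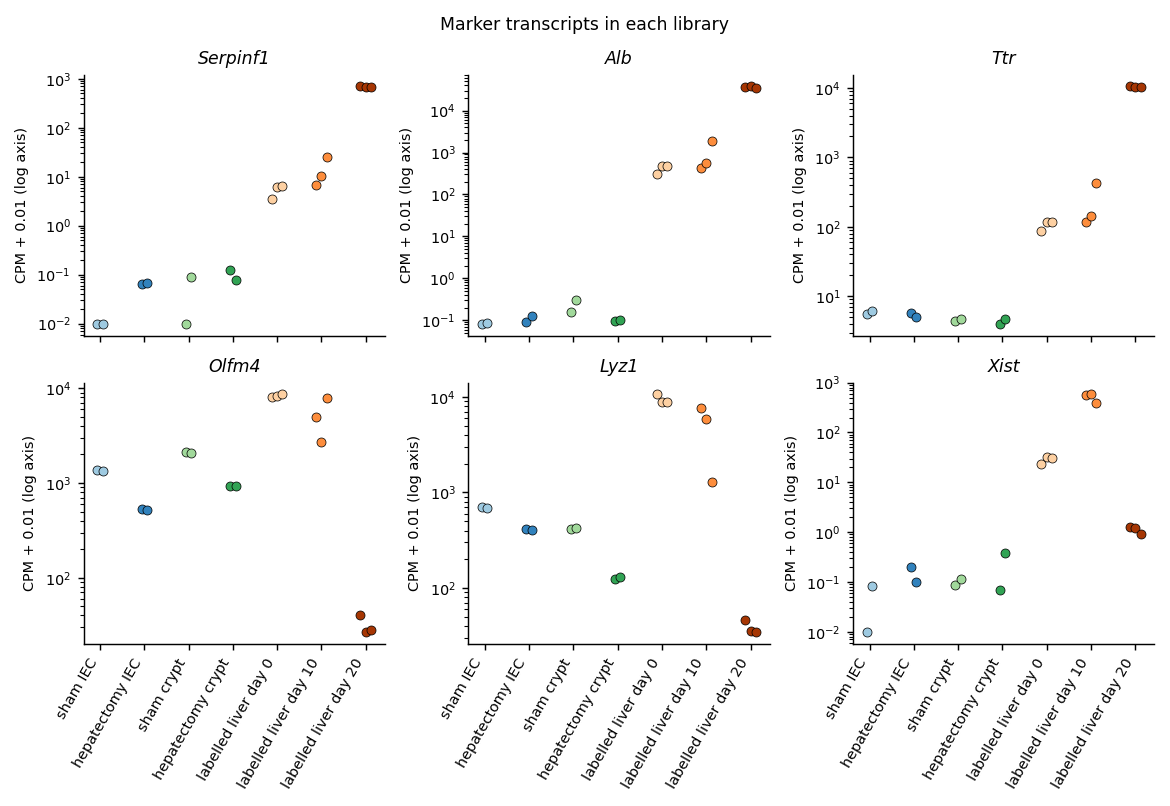
Each point is 1 library, and the log axis gives CPM of all counts plus 0.01 for Serpinf1, the hepatocyte genes Alb and Ttr, the intestinal genes Olfm4 and Lyz1, and Xist. The libraries labelled liver day 0 and day 10 sit far below day 20 for Alb and far above it for Olfm4.

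Transcripts of the sex chromosomes also separated the days. Xist, transcribed from the inactive X chromosome of female cells, stood at 23.7 ± 2.3 CPM in the libraries labelled day 0, 432 ± 170 CPM at day 10 and 1.74 ± 0.29 CPM at day 20. The Y-linked gene Eif2s3y stood at 37.1 ± 4.6, 1.01 ± 0.8 and 69.9 ± 2.6 CPM, and Ddx3y at 19.2 ± 4.9, 0.927 ± 0.45 and 69.4 ± 3.1 CPM. Kdm5d and Uty, also Y-linked, were lowest at day 10 as well, at 0.65 ± 0.8 and 0.214 ± 0.11 CPM. Of the libraries labelled day 10, replicate 3 stood apart in depth, with 12742629 counts against 28429837 and 23947162. In CPM of all counts, it also held 1110 over olfactory receptor genes, which are silent in both tissues, against 389 and 444 in the others. Its TMM factor was 1.64 against 1.16 and 1.03, so the excess is smaller in TMM-normalised CPM.

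Serpinf1 (chromosome 11, 75409769 to 75422701, minus strand, mm10) was close to absent from the intestinal libraries. It had 0 and 0 counts in sham IEC, 0 and 3 in sham crypts, 2 and 2 in hepatectomy IEC, and 4 and 3 in hepatectomy crypts. A count of 0 allows up to 3 counts per library, and such floors cover counting error only. These counts fell below the expression filter, so a change of Serpinf1 in the intestine was not detectable at this depth.

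The comparison of hepatectomy with sham in crypts asks how the crypt fraction differs after loss of liver tissue. As given below, stem cell genes as a list did not separate crypts from IEC in sham. Goblet and Paneth cell genes were lower and enterocyte genes higher in the hepatectomy crypts. By the running numbers of the libraries, sham and hepatectomy libraries form separate series, with 0 of the 4 groups holding both, so each hepatectomy effect reported here is also a difference between series. Clca1, a goblet cell product, stood at 103 ± 4.5 CPM (SD, n = 2) against 499 ± 9.9 CPM in sham crypts, and Lyz1 at 129 ± 4.2 against 342 ± 21 CPM. Fabp1, the fatty acid binding protein of enterocytes, stood at 1590 ± 21 against 295 ± 14 CPM. Olfm4 stood at 930 ± 8.5 against 1680 ± 34 CPM. Of 18207 genes tested, 3493 rose and 3329 fell, of which 1040 and 556 changed at least 2-fold.

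Among intestinal stem cell genes, 0 of 18 tested members rose, 7 fell and 11 did not pass, with the same counts when adjusted over the list alone. Olfm4 (log2 fold change -0.85 ± 0.037, adjusted p = 7.3e-09), Cd44 (-0.63 ± 0.064), Smoc2 (-0.46 ± 0.055) and Cdca7 (-0.30 ± 0.053) were among those that fell. Lgr5, the receptor that marks cycling crypt stem cells, was at 10.1 ± 2.1 against 12.8 ± 0.26 CPM (-0.32 ± 0.12, adjusted p = 0.049), a call that was lost in 7 of the 8 fits with a library left out, all but the fit without replicate 2 of the hepatectomy crypts. It was also lost with DESeq2, RLE, the stricter filter and only the groups compared. Without replicate 1 of the hepatectomy crypts the change was -0.13 (adjusted p = 0.36), and the adjusted p ranged from 0.0025 to 0.36 over the alternatives. The median over the list was -0.0885 and the list passed the set test (adjusted p = 0.016), but with adjusted p = 0.15 with an estimated correlation. Of 20 Wnt targets, 1 rose and 5 fell (1 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.59, median 0.0108, mean -0.057). Sp5 rose by 0.62 ± 0.096, whereas Glul fell (-0.47 ± 0.098). Lgr5, Ascl2, Axin2 and Cd44 are among the genes held by both the stem cell and the Wnt list. Results of these lists are therefore not independent in any comparison.

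Proliferation genes fell as groups. Of 23 mitosis genes, 22 fell and 0 rose (23 fell adjusted over the list alone), with a median of -0.64 (adjusted p = 2.2e-18). Top2a, which untangles replicated DNA, stood at 133 ± 1.5 against 204 ± 2.2 CPM (-0.62 ± 0.046), and Tpx2, a spindle assembly factor, fell by 0.78 ± 0.061 on the log2 scale. Of 24 S phase genes, 21 fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -0.43 (adjusted p = 1.3e-11). The replicative helicase subunit Mcm2 (-0.72 ± 0.053) and the ribonucleotide reductase subunits Rrm1 (-0.82 ± 0.05) and Rrm2 (-0.73 ± 0.063) were among them. Both calls held with an estimated correlation, with adjusted p = 0.0091 for mitosis and adjusted p = 0.041 for S phase genes.

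All but 1 of 17 goblet cell genes fell and 0 rose, also when adjusted over the list alone (median -1.08, adjusted p = 5.1e-42), including the mucin Muc2 at 256 ± 9 against 598 ± 4.2 CPM and Agr2 (-1.56 ± 0.044). Of 15 Paneth cell genes, 14 fell and 1 rose, also when adjusted over the list alone (median -1.22, adjusted p = 2.2e-33), with Ang4 (-2.00 ± 0.068), Itln1 (-1.20 ± 0.049) and Lyz1 (-1.41 ± 0.05) as examples. With an estimated correlation the goblet list had adjusted p = 0.016 and the Paneth list adjusted p = 0.023. Enteroendocrine genes went both ways, with 7 of 19 risen and 5 fallen, the same adjusted over the list alone (adjusted p = 0.32). The granule protein Chgb stood at 245 ± 1.6 against 143 ± 1.2 CPM and the hormone Ghrl at 18.8 ± 1 against 8.89 ± 0.48 CPM, while Gip was lower (-0.39 ± 0.052). Of 14 tuft cell genes, 0 rose and 3 fell (2 adjusted over the list alone), and the list did not pass (adjusted p = 0.46).

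Absorptive and lipid oxidation genes rose. Of 25 enterocyte genes, 23 rose and 1 fell, also adjusted over the list alone (median 1.22, adjusted p = 3.3e-73). Besides Fabp1 (2.43 ± 0.045), these included Rbp2, which binds retinol (1.51 ± 0.038), Fabp2 (1.55 ± 0.043) and Apoa1 (1.23 ± 0.04). Of 28 targets of PPAR-alpha, the fatty acid sensor, 21 rose and 1 fell, also adjusted over the list alone (median 0.60, adjusted p = 1.4e-23), among them Acadl, which oxidises long-chain fatty acids, at 136 ± 0.32 against 63 ± 0.16 CPM. Fabp1 is in both lists, so they are not fully independent. With an estimated correlation the enterocyte list had adjusted p = 0.006 and the PPAR-alpha list adjusted p = 0.033. Cholesterol synthesis genes fell, 21 of 24 with 0 risen, also adjusted over the list alone (median -0.49, adjusted p = 6.9e-16). They included Dhcr7 (-1.15 ± 0.053) and the squalene epoxidase Sqle (-0.75 ± 0.053). The cholesterol list had adjusted p = 0.02 with an estimated correlation.

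Among markers of other cell types in crypts, those of lymphocytes and red blood cells fell. Of 14 B and plasma cell genes, 11 fell and 0 rose (12 fell adjusted over the list alone; median -2.27, adjusted p = 6.4e-14), with Igha at 11.2 ± 1.1 against 50.4 ± 1.7 CPM. Of 17 T and NK cell genes, 16 fell and 0 rose, also adjusted over the list alone (median -1.50, adjusted p = 1.4e-13), with the granzymes Gzmb (-1.70 ± 0.12) and Gzma (-1.28 ± 0.09). Of 7 erythroid genes, 4 fell and 0 rose (5 fell adjusted over the list alone; adjusted p = 0.00016), led by the haemoglobin genes Hba-a1 (-1.35 ± 0.074) and Hbb-bs (-1.18 ± 0.12), near-identical copies of their neighbours whose counts are uncertain. Of 12 fibroblast genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.09), except without replicate 1 of the hepatectomy crypts (adjusted p = 0.047). Dcn, a matrix proteoglycan, was at 4.4 ± 0.7 against 0.33 ± 0.032 CPM. Macrophage genes (1 of 11 risen, 4 fallen, adjusted p = 0.32), neutrophil genes (1 of 5 risen, adjusted p = 0.93) and endothelial genes (0 of 9 risen or fallen, adjusted p = 0.74) did not pass, with the same counts adjusted over each list alone. Smooth muscle genes (1 of 5 risen and 2 fallen, also adjusted over the list alone) did not pass either (adjusted p = 0.74), with a median of 0.0825 and a mean of 0.32 but a downward test.

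Clock genes stood out among single genes. The 6 largest rises were Exosc6, Dbp, Tef, C3, Mt2 and Nr1d1, of which Dbp, Tef and Nr1d1 are output or core genes of the circadian clock. Dbp was at 11.6 ± 1.7 against 0.521 ± 0.072 CPM, Tef at 18.8 ± 1.3 against 1.55 ± 0.45 CPM and Nr1d1 at 55.9 ± 5.9 against 8.39 ± 0.72 CPM, while the core activator Arntl was at 15.9 ± 0.64 against 38.2 ± 1.2 CPM. Of 16 clock genes, 8 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.00064, and adjusted p = 0.13 with an estimated correlation). C3, a complement protein, and Mt2, a metallothionein, rose by 2.90 ± 0.17 and 2.85 ± 0.094. Exosc6 had 0 counts in both sham crypt libraries and a mean of 14.1 CPM in the hepatectomy crypts. By that mean it was at least 160-fold higher, a bound that leaves out the spread between the hepatectomy libraries, and its call was lost with DESeq2. The 6 largest falls were Defa35 (-6.58 ± 0.31), the mast cell proteases Mcpt1 (-4.95 ± 0.25) and Mcpt2 (-4.51 ± 0.29), Rps3a3, Stox2 and Pla2g4c. Defa35, Mcpt1, Mcpt2 and Rps3a3 belong to families with near-identical copies, and Exosc6, Dbp, Tef, Mt2, Nr1d1, Rps3a3, Stox2 and Pla2g4c overlap another annotated gene, so their counts are uncertain.

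Partners named for PEDF were measured in the same crypts. Ppara, which encodes PPAR-alpha (chromosome 15, 85734983 to 85802819, plus strand), stood at 28.6 ± 0.067 against 19.9 ± 0.91 CPM (0.53 ± 0.074, adjusted p = 0.00017). Lrp5 (chromosome 19, 3584828 to 3686564, minus strand), a Wnt co-receptor, rose by 0.79 ± 0.087 (adjusted p = 2.5e-05). Its relative Lrp6 rose by 0.41 ± 0.098, and by 0.24 without replicate 1 of the hepatectomy crypts, where the call was lost. Pnpla2, the triglyceride lipase, did not pass (91.1 ± 1.3 against 90.9 ± 0.44 CPM, adjusted p = 0.98). Of the 5 tested members of this list, 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.047, and adjusted p = 0.18 with an estimated correlation). The list also lost its call with the replicate block, where 15 lists passed in place of 16. The call of the list was lost in 6 of the 8 fits with a library left out, with adjusted p = 0.11 without replicate 1 of the hepatectomy crypts. The fourth, Rpsa, overlaps a small nucleolar RNA gene and is uncertain, and its call was lost in 5 of the 8 fits with a library left out. Its change was 0.12 (adjusted p = 0.29; 0.0057 to 0.29 over the alternatives) without replicate 1 of the hepatectomy crypts, against 0.24 with all libraries.

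The other lists past the set test in crypts were those of ileal bile acid handling, the unfolded protein response and lipogenesis. Of 10 bile acid genes, 6 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0066, and adjusted p = 0.20 with an estimated correlation). Abcc2, an efflux pump, rose by 1.91 ± 0.058, whereas Slc10a2, the ileal bile acid importer, fell by 1.62 ± 0.15 on the log2 scale, as did Fabp6 (-0.86 ± 0.075). Of 16 unfolded protein response genes, 2 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.20 with an estimated correlation). Of 19 lipogenesis genes, 4 rose and 9 fell (4 and 11 adjusted over the list alone; adjusted p = 0.035, and adjusted p = 0.27 with an estimated correlation). That call was lost without replicate 1 of the sham crypts (adjusted p = 0.051) or replicate 2 of the hepatectomy crypts (adjusted p = 0.077).

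The hepatectomy libraries of both fractions also carried more counts over genes that are silent in gut epithelium. They detected 29786 to 30461 genes against 24420 to 26186 in sham. Over olfactory receptor genes they held 131 to 164 CPM of all counts against 62.5 to 82.3 CPM. Low-level rises, such as those of fibroblast genes, therefore lie beside this background. The share of mitochondrial counts was 4 to 4.41% in sham crypts and 7.3 to 10.1% in the other intestinal libraries. The Gm10800 transcript took 0.0717 to 0.102% of sham crypt counts against 1.83% or more elsewhere. By these shares the hepatectomy crypts stood nearer to IEC than to sham crypts. Their higher enterocyte and lower mitosis genes also point towards IEC, whereas their lower Paneth cell and erythroid genes point away. The purity of the crypt fractions was not tested, so it is not separated from the hepatectomy effect in crypts.

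**Figure D2:**
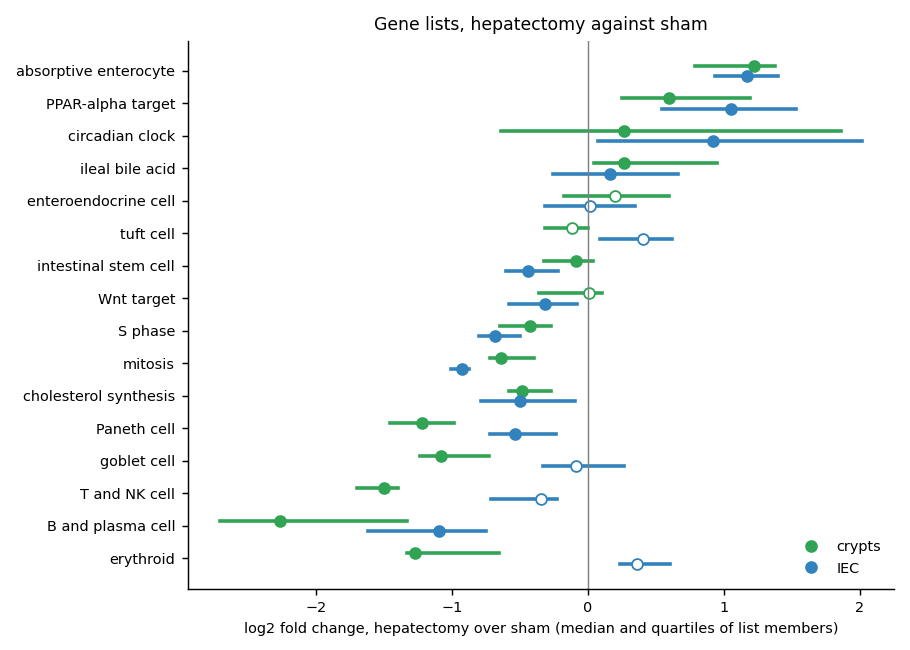
Points are medians and lines are quartiles of the log2 fold change of list members, hepatectomy over sham (2 libraries each), in crypts and IEC; filled points passed the set test at an adjusted p under 0.05. Enterocyte and PPAR-alpha target genes lie to the right and mitosis genes to the left in both fractions, whereas the goblet cell list passed the test in crypts and did not in IEC.

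In IEC, the comparison of hepatectomy with sham asks the same of the whole epithelial lining. Alpi, the alkaline phosphatase of the enterocyte brush border, stood at 2060 ± 67 against 599 ± 5 CPM (SD, n = 2), and Acadl at 236 ± 4.2 against 77.7 ± 1.3 CPM. Proliferation and stem cell genes were lower, with Top2a at 63.5 ± 1.6 against 129 ± 2.5 CPM and Olfm4 at 633 ± 5.8 against 1400 ± 1.9 CPM. Of 18207 genes, 3543 rose and 3334 fell, of which 1035 and 396 changed at least 2-fold. The balance of all calls turned with DESeq2 (2517 and 2656) and without the filter (3368 and 4040). It also turned without replicate 1 of the sham crypts (3155 and 3612), of the sham IEC (2659 and 2665) or of the hepatectomy crypts (3556 and 3598), and without replicate 2 of the hepatectomy crypts (3565 and 3606).

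All 25 enterocyte genes rose, also adjusted over the list alone (median 1.17, adjusted p = 9.6e-71), among them Cyp3a11 (2.37 ± 0.057), Apoa4 (1.55 ± 0.044) and Apoa1 (1.38 ± 0.04). Of 28 PPAR-alpha targets, 25 rose and 1 fell (26 and 1 adjusted over the list alone; median 1.05, adjusted p = 1.9e-39), including Acadl (1.60 ± 0.047) and the transcription factor Creb3l3 (1.70 ± 0.053). Ppara itself was at 45.1 ± 2.2 against 20.8 ± 1.5 CPM (1.11 ± 0.076, adjusted p = 2.3e-07). Lrp5 (0.15 ± 0.1, adjusted p = 0.27) and Lrp6 (-0.11 ± 0.1, adjusted p = 0.45) did not pass. Of 5 listed PEDF partners, 1 rose and 2 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.60), with a median of -0.11 and a mean of 0.14. Pnpla2 (-0.20 ± 0.059) and Rpsa (-0.27 ± 0.082) passed in the full data but lost the call in some of the alternatives.

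Of the cell cycle genes, all 23 mitosis genes fell, also adjusted over the list alone (median -0.93, adjusted p = 1.2e-29), with Cdc20 (-0.97 ± 0.05) and Ccna2 (-1.06 ± 0.061) as examples. Of 24 S phase genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone; median -0.68, adjusted p = 4.7e-14), led by Mcm2 (-0.84 ± 0.055) and Uhrf1 (-0.82 ± 0.055). Of 18 stem cell genes, 13 fell and 0 rose, also adjusted over the list alone (median -0.44, adjusted p = 8.7e-07), including Olfm4 (-1.15 ± 0.037), Cd44 (-1.06 ± 0.075) and Prom1 (-0.49 ± 0.048). These 3 calls held with an estimated correlation. Of 20 Wnt targets, 9 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0052, and adjusted p = 0.099 with an estimated correlation), with Ccnd1, the G1 cyclin, at 51.9 ± 2.6 against 139 ± 1.9 CPM and Sp5 higher by 0.81 ± 0.085.

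Of 15 Paneth cell genes, 11 fell and 2 rose, also adjusted over the list alone (median -0.54, adjusted p = 1.1e-06, and adjusted p = 0.18 with an estimated correlation). Itln1 fell (-0.87 ± 0.048), as did the defensins Defa22 (-1.23 ± 0.065) and Defa21 (-1.04 ± 0.065), which share sequence with other defensins and are uncertain. Of 17 goblet cell genes, 4 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.50). Guca2a, the guanylin precursor, stood at 784 ± 3.2 against 422 ± 0.53 CPM and Zg16 at 2230 ± 130 against 1340 ± 12 CPM, while Klk1 (-1.20 ± 0.06) and Agr2 (-0.55 ± 0.044) were lower. Of 19 enteroendocrine genes, 6 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.90, median 0.017, mean -0.0422). The hormone gene Gcg was at 11.3 ± 0.33 against 34.2 ± 1.9 CPM and Gip at 271 ± 9.8 against 149 ± 5.2 CPM. Of 14 tuft cell genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.18).

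Among markers of other cell types, B and plasma cell genes fell, 10 of 14 with 0 risen (11 fell adjusted over the list alone; median -1.10, adjusted p = 5.6e-09), with Igha at 75.6 ± 2.1 against 284 ± 4.6 CPM and Jchain (-2.01 ± 0.098). T and NK cell genes did not pass as a list (0 of 17 risen and 5 fallen, also adjusted over the list alone; adjusted p = 0.054), but did in 6 of the 8 fits with a library left out, with adjusted p = 0.036 without replicate 1 or 2 of the hepatectomy crypts. Of 7 erythroid genes, 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.24), with Hba-a2 at 88.8 ± 4.5 against 58.9 ± 2.8 CPM. Fibroblast genes (3 of 12 risen, 1 fallen, adjusted p = 0.50) and neutrophil genes (3 of 5 risen, 1 fallen, adjusted p = 0.29) did not pass, with the same counts adjusted over each list alone. Of 9 endothelial genes, 3 rose (0 adjusted over the list alone) and the list did not pass (adjusted p = 0.50). Macrophage genes (3 of 11 risen, 2 fallen, also adjusted over the list alone, adjusted p = 0.46) had a median of 0.0729 and a mean of 0.26 with a downward test. Smooth muscle genes (0 of 5 risen and 2 fallen, also adjusted over the list alone, adjusted p = 0.50) had a median of 0.29 with a mean of -0.12.

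Further lists passed in IEC. Of 24 cholesterol synthesis genes, 16 fell and 3 rose, also adjusted over the list alone (median -0.50, adjusted p = 1.7e-09, and adjusted p = 0.058 with an estimated correlation), with Sqle at 45.6 ± 1 against 81.4 ± 1 CPM. Of 19 lipogenesis genes, 11 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.00021, and adjusted p = 0.12 with an estimated correlation). The desaturase Scd2 was at 31.1 ± 0.56 against 134 ± 2.8 CPM and Fasn, the fatty acid synthase, at 36.3 ± 0.014 against 74.3 ± 5.2 CPM, whereas Dgat2 rose by 1.42 ± 0.054. Of 9 MHC class II genes, 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00046, and adjusted p = 0.18 with an estimated correlation), with H2-Aa at 697 ± 1.8 against 428 ± 3.8 CPM. Of 18 immediate early and heat shock genes, 10 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.19 with an estimated correlation). Fos was at 117 ± 0.74 against 36.2 ± 3 CPM, while the heat shock gene Hsph1 was lower (-0.92 ± 0.066). Ileal bile acid genes (5 of 10 risen, 3 fallen, and 6 and 3 adjusted over the list alone) passed with adjusted p = 0.0072, and adjusted p = 0.18 with an estimated correlation. Antimicrobial genes (10 of 17 risen, 5 fallen, also adjusted over the list alone) passed with adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation. That call was lost without replicate 1 (adjusted p = 0.092) or 2 (adjusted p = 0.071) of the sham IEC.

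Clock genes moved in IEC as well, more of them upward. Of 16, 11 rose and 3 fell, also adjusted over the list alone (median 0.92, adjusted p = 8.9e-06, and adjusted p = 0.07 with an estimated correlation). Dbp, at 31.9 ± 11 against 0.853 ± 0.15 CPM, rose most of the named genes in IEC, Tef stood at 28 ± 1.9 against 4.68 ± 0.71 CPM, and Arntl was lower (-1.57 ± 0.074). The next rises were Erdr1 (4.98 ± 0.32), G0s2, an inhibitor of triglyceride lipolysis (4.95 ± 0.43), the PPAR-alpha target Cyp4a10 (3.71 ± 0.21), Gdpd3 and Slc6a3. Mcpt1 (-3.75 ± 0.27), Gsdmc3, Gsdmc4 and the gastric-type genes Gkn2 (-3.56 ± 0.2), Gkn1 (-3.28 ± 0.19) and Tff1 (-3.24 ± 0.16) fell most. Stomach tissue in the sham IEC was not tested for. Mcpt1, Gsdmc3 and Gsdmc4 have close relatives, and Dbp, Tef, G0s2, Gdpd3 and Tff1 overlap another gene, so their counts are uncertain.

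**Figure D3:**
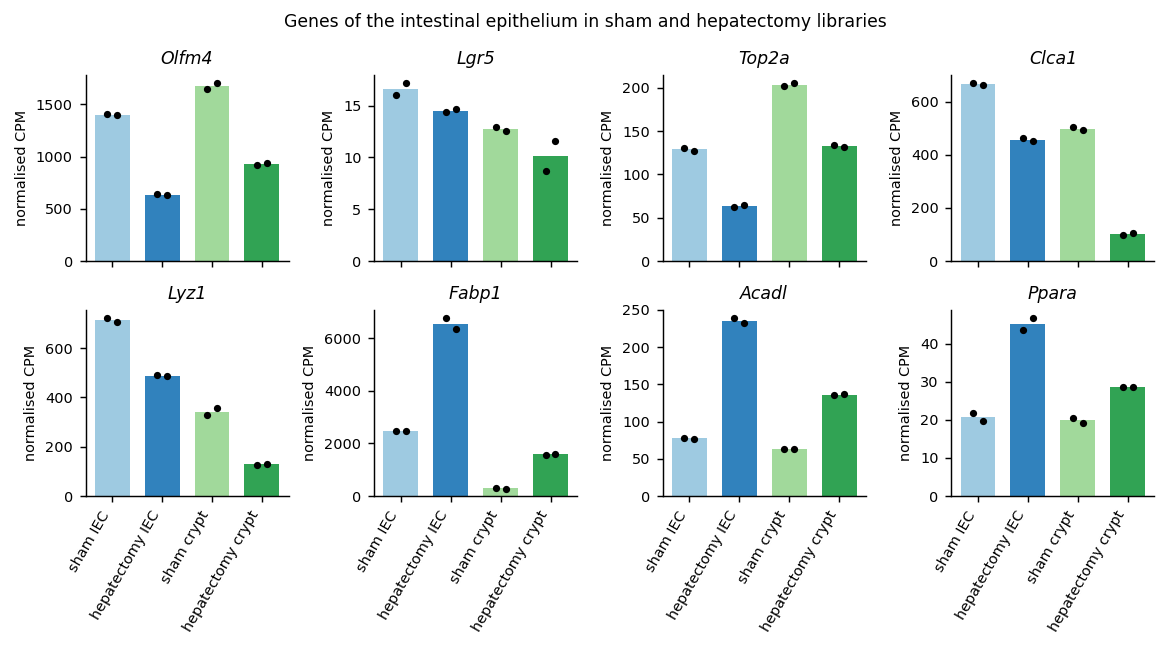
Bars are group means and points the 2 libraries of each group, in TMM-normalised CPM on axes that start at 0, for stem cell (Olfm4, Lgr5), mitosis (Top2a), goblet (Clca1), Paneth (Lyz1), enterocyte (Fabp1) and lipid oxidation (Acadl, Ppara) genes. In both fractions Fabp1, Acadl and Ppara are higher and Olfm4, Top2a and Clca1 lower in the hepatectomy libraries.

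Whether the hepatectomy effect differed between crypts and IEC was tested directly, as the crypt effect minus the IEC effect. Goblet cell genes had the smallest adjusted p of the lists, though not the largest median, with 13 of 17 having a lower effect in crypts and 0 a higher one, also adjusted over the list alone (median -1.02, adjusted p = 4e-44). Zg16 was lower in hepatectomy crypts but higher in hepatectomy IEC (difference -2.01 ± 0.067, adjusted p = 1.4e-08), and so was Guca2a (-1.62 ± 0.057). Mitosis genes fell less in crypts, with a higher effect for 14 of 23 and a lower one for 0 (17 adjusted over the list alone; median 0.28, adjusted p = 3.3e-07), led by Mki67 (0.83 ± 0.093). Of 18207 genes, 1666 had a higher and 1833 a lower effect in crypts, of which 313 and 398 differed at least 2-fold. The balance of all calls turned to 1350 and 999 without replicate 1 of the sham crypts and to 1963 and 1777 without the filter. It turned as well with DESeq2 (1274 and 1134) and RLE (1758 and 1664), and without replicate 2 of the sham crypts (1271 and 1236) or replicate 1 or 2 of the hepatectomy crypts (1536 and 1356, 1612 and 1487).

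Lower effects in crypts were found for T and NK cell genes (11 of 17, and 12 adjusted over the list alone, adjusted p = 1.3e-08) and erythroid genes (4 of 7, also adjusted over the list alone, adjusted p = 1.4e-09), with 0 higher in either list. These calls, like those of the goblet and mitosis lists, held with an estimated correlation. Another 10 lists passed with the preset correlation and not with an estimated one, while fry, a rotation test, called all 14. Paneth cell genes had lower effects in crypts (11 of 15 lower, 1 higher, also adjusted over the list alone; adjusted p = 3.1e-14, and adjusted p = 0.11 with an estimated correlation). MHC class II genes did too (6 of 9 lower, 0 higher, also adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.11 with an estimated correlation). The same was found for immediate early and heat shock genes (7 of 18 lower, 9 adjusted over the list alone, 0 higher; adjusted p = 4.1e-06, and adjusted p = 0.11 with an estimated correlation). PPAR-alpha targets had lower effects as well (12 of 28 lower, 14 adjusted over the list alone, 2 higher in both; adjusted p = 4.9e-05, and adjusted p = 0.17 with an estimated correlation). Tuft cell genes had lower effects (4 of 14, with 1 higher, also adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.12 with an estimated correlation). B and plasma cell genes also had lower effects (4 of 14, 8 adjusted over the list alone, 0 higher; adjusted p = 0.019, and adjusted p = 0.21 with an estimated correlation). Mmp7 (-1.47 ± 0.082), Ang4 (-1.52 ± 0.088) and Fos (-1.61 ± 0.093) are examples.

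Higher effects in crypts were found for stem cell genes (8 of 18, 11 adjusted over the list alone, 0 lower; adjusted p = 0.0012, and adjusted p = 0.11 with an estimated correlation). Wnt targets followed (6 of 20 higher and 0 lower, and 7 and 1 adjusted over the list alone; adjusted p = 0.0071, and adjusted p = 0.11 with an estimated correlation). S phase genes had higher effects (6 of 24, 9 adjusted over the list alone, 0 lower; adjusted p = 0.018, and adjusted p = 0.34 with an estimated correlation), a call lost without replicate 2 of the hepatectomy IEC (adjusted p = 0.067). Lipogenesis genes did as well (8 of 19 higher, 10 adjusted over the list alone, 3 lower in both; adjusted p = 0.018, and adjusted p = 0.28 with an estimated correlation). Ccnd1 (1.44 ± 0.069) and Axin2 (0.73 ± 0.1), a feedback inhibitor of Wnt signalling, were among them. Ppara rose less in crypts than in IEC (-0.59 ± 0.11, adjusted p = 0.0023), and Lrp5 more (0.64 ± 0.13, adjusted p = 0.0057). Enterocyte genes went both ways (6 of 25 higher, 11 lower, and 7 and 12 adjusted over the list alone, adjusted p = 0.36), as did enteroendocrine genes (7 of 19 higher, 5 lower, and 9 and 5 adjusted over the list alone, adjusted p = 0.36). Fibroblast (1 of 12 higher, 1 lower, and 2 and 1 adjusted over the list alone, adjusted p = 0.69) and macrophage genes (2 of 11 higher, 2 lower, and 3 and 2 adjusted over the list alone, adjusted p = 0.76, median -0.30 with an upward test) did not pass. Neutrophil (0 of 5 higher, 1 lower, adjusted p = 0.30), endothelial (0 of 9 either way, adjusted p = 0.69) and smooth muscle genes (0 of 5 either way, adjusted p = 0.72) did not pass either, also adjusted over each list alone.

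In sham mice, crypts were compared with IEC to show what the fractions hold. All 25 enterocyte genes were lower in crypts, also adjusted over the list alone (median -2.20, adjusted p = 3.8e-174), with Apoa4 at 367 ± 12 against 6450 ± 150 CPM (SD, n = 2). All 23 mitosis genes were higher, also adjusted over the list alone (median 0.64, adjusted p = 2.1e-14), with Ube2c at 181 ± 4.7 against 97.1 ± 1.6 CPM. Stem cell genes were mixed, with 8 of 18 higher and 5 lower (9 and 8 adjusted over the list alone, adjusted p = 0.47), and Cd44 was at 40.5 ± 0.83 against 23.5 ± 0.75 CPM. Paneth cells sit at the crypt base, yet 13 of 15 Paneth cell genes were lower in crypts and 0 higher, also adjusted over the list alone (median -1.62, adjusted p = 1.6e-32). The defensin Defa21, uncertain because of its close relatives, was at 87.9 ± 8 against 472 ± 17 CPM. As lists, stem and Paneth cell markers therefore do not show the crypt fraction to be enriched in cells of the crypt base. Of 18207 genes, 3523 were higher and 3512 lower in crypts. The calls were even, and their balance turned in several alternatives, such as RLE (3309 and 3670), but of those that differed at least 2-fold 399 were higher and 1247 lower in crypts.

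Other groups separated the sham fractions as well. Tuft cell genes (13 of 14, adjusted p = 2.3e-12) and enteroendocrine genes (13 of 19, adjusted p = 8e-09) were lower in crypts with 0 higher, also adjusted over each list alone, among them Trpm5 (-1.62 ± 0.083), which overlaps another gene and is uncertain, and the hormone genes Nts (-1.87 ± 0.066) and Sct (-1.59 ± 0.057). Erythroid genes (5 of 7, adjusted p = 2.5e-18) were lower with 0 higher, also adjusted over the list alone, with Hba-a1 at 14.9 ± 0.49 against 135 ± 2.2 CPM, and so were B and plasma cell genes (8 of 14, and 9 adjusted over the list alone, adjusted p = 1.7e-07). PPAR-alpha targets (21 of 28 lower and 2 higher, and 24 and 2 adjusted over the list alone, adjusted p = 1.2e-16) and ileal bile acid genes (7 of 10 lower and 0 higher, also adjusted over the list alone, adjusted p = 4.3e-10) were lower. S phase genes were higher (20 of 24, and 22 adjusted over the list alone, with 1 lower; adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation), as were MHC class II genes (8 of 9, also adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.10 with an estimated correlation). Cholesterol synthesis genes were higher (16 of 24 with 2 lower, and 18 and 3 adjusted over the list alone; median 0.39, adjusted p = 1.1e-05, and adjusted p = 0.10 with an estimated correlation), with Sqle at 131 ± 0.48 against 81.4 ± 1 CPM. Goblet cell genes (4 of 17 higher, 6 lower, also adjusted over the list alone, adjusted p = 0.97) and Wnt targets (4 of 20 higher, 7 lower, and 5 and 7 adjusted over the list alone, adjusted p = 0.87) did not pass. The same holds for T and NK cell (1 of 17 higher, 5 lower, adjusted p = 0.57), fibroblast (0 of 12 higher, 1 lower, adjusted p = 0.87) and endothelial genes (0 of 9 higher, 3 lower, adjusted p = 0.47), with the same counts adjusted over each list alone. Macrophage genes (3 of 11 higher, 5 lower, and 3 and 7 adjusted over the list alone) had adjusted p = 0.87. Neutrophil and smooth muscle genes (1 of 5 higher and 0 lower in each, also adjusted over each list alone) both had adjusted p = 0.87, with medians of -0.47 and -0.24 and an upward test. The largest differences were those of Tgtp1 (3.99 ± 0.15), Rps3a3 (3.73 ± 0.1) and Iigp1 (3.46 ± 0.26) on the crypt side and Akp3 (-4.51 ± 0.077), Rdh16f2 (-4.50 ± 0.26) and Leap2 (-4.15 ± 0.062) on the IEC side, of which Tgtp1 and Rps3a3 have close copies and are uncertain.

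For the libraries labelled liver, the question was how Serpinf1 and liver genes changed over the days of DSS. Serpinf1 stood at 4.32 ± 0.99 CPM (SD, n = 3) at day 0, 10.5 ± 4.9 CPM at day 10 and 1040 ± 22 CPM at day 20. Its log2 fold change was 1.27 ± 0.3 at day 10 (adjusted p = 0.0075) and 7.92 ± 0.38 at day 20 (adjusted p = 7.7e-10) against day 0, and 6.64 ± 0.36 at day 20 against day 10 (adjusted p = 2.7e-09). An exact two-sided permutation test gave p = 0.1 for each pair of days, the smallest value that 3 against 3 libraries allow. The rise at day 10 had the direction of the median rise (0.99) of the 26 hepatocyte secreted protein genes, of which Serpinf1 is 1, and was larger. Whether it differed from the rise of those genes was not tested, so it is not read as a change of its own. The change at day 10 was 0.77 (adjusted p = 0.082) in a fit of day 0 and day 10 alone without replicate 3 of day 10. Because the libraries labelled day 0 and day 10 hold intestinal transcripts, a difference from day 20 is also a difference between tissues, and no direction over time in the liver can be read from it.

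Between the libraries labelled liver day 10 and day 0, antigen presentation, interferon and proliferation genes were lower and stress genes higher at day 10. H2-Aa, an MHC class II chain, stood at 105 ± 39 against 775 ± 140 CPM (SD, n = 3), the interferon-induced gene Bst2 at 11.5 ± 3 against 53.7 ± 8.9 CPM, and the heat shock gene Hspa1b at 169 ± 31 against 17.7 ± 2.6 CPM. The transcripts of the sex chromosomes given above differ between the same libraries (of 5 genes 1 rose and 4 fell, also adjusted over the list alone; adjusted p = 3.1e-06, and adjusted p = 0.12 with an estimated correlation). Each difference of day 10 from another day is therefore also a difference in sex chromosome transcripts, and these libraries cannot separate the day from it. Of 16694 genes, 4129 rose and 3146 fell, of which 3095 and 384 changed at least 2-fold. In a fit of these days alone the split turned to 2136 risen and 3389 fallen, and without the filter to 4204 and 4310, so the balance of directions depends on the samples and genes in the fit.

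The list results for these days rest on the preset correlation. With an estimated correlation, camera called 0 of 34 lists (lowest adjusted p = 0.12), with 6 at an unadjusted p under 0.05, and fry called 18. Of 9 MHC class II genes, 8 fell and 0 rose, also adjusted over the list alone (median -2.38, adjusted p = 4e-20). Of 26 interferon response genes, 14 fell and 1 rose (16 and 1 adjusted over the list alone, adjusted p = 2.3e-11), including Bst2 (-2.23 ± 0.2) and the guanylate binding protein Gbp3 (-3.37 ± 0.3). Of 24 S phase genes, 23 fell and 0 rose, also adjusted over the list alone (median -0.93, adjusted p = 2.4e-14), and of 23 mitosis genes 16 fell and 1 rose, also adjusted over the list alone (adjusted p = 5.3e-07), with Rrm1 (-1.28 ± 0.16) and Aurkb (-1.08 ± 0.17). Of 24 cholesterol synthesis genes, 21 fell and 0 rose, also adjusted over the list alone (adjusted p = 2e-13), with Dhcr7 at 38.3 ± 8.3 against 82.7 ± 5 CPM. Of 18 immediate early and heat shock genes, 16 rose and 0 fell (17 adjusted over the list alone; median 1.23, adjusted p = 1.4e-17), among them Egr1 (1.45 ± 0.15) and Nr4a1 (1.96 ± 0.21).

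Liver genes rose at low levels. Of 26 secreted protein genes, 22 rose and 0 fell (24 adjusted over the list alone). The median was 0.99 (adjusted p = 0.00011, and adjusted p = 0.57 with an estimated correlation). The complement and coagulation list (27 of 31 risen, 0 fallen, also adjusted over the list alone) and the cytochrome P450 list (22 of 31 risen, 0 fallen, and 25 adjusted over the list alone) behaved alike, with adjusted p = 0.00014 and 0.00011, and adjusted p = 0.57 with an estimated correlation in both. As a median over those 26 secreted protein genes, day 0 held 0.544% and day 10 1.16% of the day 20 level. Per library the level was 0.471 to 0.587% at day 0 and 0.668, 0.904 and 1.83% at day 10, highest in replicate 3. Without replicate 3 of day 10, 6 lists rose in place of 15. The lists of secreted proteins, complement and coagulation, and cytochrome P450 kept the call. Those of bile acid synthesis (adjusted p = 0.23), gluconeogenesis (adjusted p = 0.058), amino acids and the urea cycle (adjusted p = 0.22), male-biased (adjusted p = 0.08) and female-biased liver genes (adjusted p = 0.16) and the growth hormone axis (adjusted p = 0.23) lost it, as did the erythroid, PPAR-alpha and clock lists. In a fit of these days alone without replicate 3, Igf1, C9, F13b, Itih3, Apoc3 and Masp1 lost the call. Apoc3 is also in the risen enterocyte list. Of 30 PPAR-alpha targets, 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.50 with an estimated correlation; lost in 7 of the 9 fits with a library left out, with adjusted p = 0.064 without replicate 3 of day 10), including Pdk4 (2.71 ± 0.29) and Angptl4 (1.43 ± 0.17), and Ppara rose by 0.95 ± 0.15. Of 33 acute phase genes, 20 rose and 4 fell (21 and 4 adjusted over the list alone) without passing as a list (adjusted p = 0.17, but 0.0055 without replicate 1 of day 10), with Mt2 lower (-2.30 ± 0.2) and Cebpb higher (2.42 ± 0.37). Wnt targets did not pass (4 of 21 risen, 3 fallen, also adjusted over the list alone, adjusted p = 0.74, median 0.11 with a downward test).

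Endothelial genes (17 of 20, also adjusted over the list alone, adjusted p = 2.4e-05) and fibroblast genes (13 of 20, and 16 adjusted over the list alone, adjusted p = 9.7e-05) rose with 0 fallen, and both had adjusted p = 0.50 with an estimated correlation. Kdr, a receptor of endothelial cells, was at 1.7 ± 1.3 against 0.209 ± 0.094 CPM. Both calls held without replicate 3 of day 10, which also has the raised counts over silent genes given above. Of 9 erythroid genes, 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0064, and adjusted p = 0.50 with an estimated correlation), a call lost without replicate 3 of day 10 (adjusted p = 0.062). T and NK cell genes (0 of 12 risen, 3 fallen, adjusted p = 0.13), B and plasma cell genes (3 of 7 risen, adjusted p = 0.25), neutrophil genes (2 of 6 risen, 1 fallen, adjusted p = 0.74) and macrophage genes (7 of 19 risen, 2 fallen, adjusted p = 0.11) did not pass. Adjusted over each list alone, these counts differed only for macrophage genes, of which 8 rose. T and NK cell genes passed without replicate 3 of day 10 (adjusted p = 0.018) and macrophage genes without replicate 1 (adjusted p = 0.018). Cholangiocyte genes did not pass (2 of 13 risen, 3 fallen, and 2 and 2 adjusted over the list alone, adjusted p = 0.46), with a median of -0.19 and a mean of 0.34. The largest rises were those of Slc28a1, Scgb2b17, Pla2g4c, Jaml, Xist and Pnliprp1, from 4.61 ± 0.63 to 3.64 ± 0.68, and the largest falls those of Tgtp2 (-5.48 ± 0.43), Uty, Eif2s3y, Tgtp1, Ubd (-5.12 ± 0.29) and Gbp2 (-4.59 ± 0.43), of which Tgtp1 and Tgtp2 are near-identical and uncertain.

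Between the libraries labelled liver day 20 and day 0, genes of liver functions were higher and proliferation genes and most cholangiocyte genes lower at day 20. Hamp, the iron hormone hepcidin, stood at 805 ± 2.6 against 2.12 ± 0.17 CPM (SD, n = 3), the lipase gene Mgll at 254 ± 4 against 3.23 ± 0.16 CPM, and Ccna2, a mitotic cyclin, at 1.8 ± 0.42 against 220 ± 32 CPM. Of 16694 genes, 5558 rose and 6356 fell, of which 4370 and 4790 changed at least 2-fold, with a median of -0.16 over all genes. As stated for Serpinf1, these libraries differ in tissue content. They also differ in sex chromosome transcripts, with Xist at 1.74 ± 0.29 against 23.7 ± 2.3 CPM and Ddx3y at 69.4 ± 3.1 against 19.2 ± 4.9 CPM. Changes between these days, those of male-biased liver genes included, cannot be separated from either difference.

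With an estimated correlation, camera called 0 of 34 lists for day 20 against day 0 (lowest adjusted p = 0.082), with 12 at an unadjusted p under 0.05, and fry called 30, so the set tests below hold with the preset correlation. All 26 hepatocyte secreted protein genes (median 7.52, adjusted p = 4e-20), all 31 complement and coagulation genes (median 7.42, adjusted p = 1.7e-23) and all 31 cytochrome P450 genes (median 7.56, adjusted p = 1.7e-22) rose, also adjusted over each list alone. Of 31 amino acid and urea cycle genes, 29 rose and 1 fell, and of 24 bile acid genes, 23 rose and 1 fell, in both cases also adjusted over the list alone (adjusted p = 2.6e-20 and 5.6e-18). Igfals (6.99 ± 0.26), F5 (7.33 ± 0.27), Fah (7.31 ± 0.24) and the nuclear receptor Nr0b2 (6.35 ± 0.19) were among them. Of 30 PPAR-alpha targets, 29 rose and 0 fell, also adjusted over the list alone (median 3.26, adjusted p = 1.8e-16), with Mgll (6.29 ± 0.2) and Angptl4 (5.34 ± 0.19), and Ppara was at 222 ± 4.5 against 8.52 ± 1.3 CPM. All 20 male-biased liver genes rose, also adjusted over the list alone (median 7.76, adjusted p = 8.3e-18, and adjusted p = 0.14 with an estimated correlation), led by Hsd3b5 (8.43 ± 0.24). Gluconeogenesis genes rose (13 of 14, and 14 adjusted over the list alone, 0 fell; median 5.70, adjusted p = 8.2e-11, and adjusted p = 0.12 with an estimated correlation), with Pck1 at 2030 ± 100 against 16.4 ± 1.2 CPM. So did lipogenesis genes (18 of 21, with 1 fallen, also adjusted over the list alone; median 2.49, adjusted p = 2.5e-09, and adjusted p = 0.082 with an estimated correlation), with Me1 rising by 6.07 ± 0.17. Of 33 acute phase genes, 28 rose and 5 fell, also adjusted over the list alone (median 4.93, adjusted p = 4.3e-07), with Crp rising by 7.33 ± 0.33 and Cd14 falling (-4.83 ± 0.19). All 23 mitosis genes (median -6.05, adjusted p = 1.6e-25) and 22 of 24 S phase genes (1 rose, adjusted p = 4e-19) fell, also adjusted over each list alone. Of 21 Wnt targets, 12 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.0017), with Ascl2, a stem cell factor, lower (-7.01 ± 0.25) and Cd44 lower (-4.44 ± 0.15).

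Markers of other liver cells rose too, with 20 of 20 endothelial genes (adjusted p = 9.9e-10), 19 of 20 fibroblast and stellate genes (0 fell, adjusted p = 6.7e-06) and 16 of 19 macrophage genes (3 fell, adjusted p = 0.0014). Clec4g (7.23 ± 0.37) and Dcn (7.38 ± 0.41) were examples, as was the Kupffer cell gene Cd5l (6.33 ± 0.37). Of 13 cholangiocyte genes, which are largely shared with gut epithelium, 10 fell and 2 rose (adjusted p = 1.7e-08), including Tspan8 (-6.64 ± 0.21) and Elf3 (-6.69 ± 0.24). Erythroid genes rose (6 of 9, 1 fell, adjusted p = 0.0032), and these counts were the same adjusted over each list alone. T and NK cell genes (2 of 12 risen and 3 fallen, and 1 and 2 adjusted over the list alone, adjusted p = 0.90), B and plasma cell genes (2 of 7 risen and 1 fallen, also adjusted over the list alone, adjusted p = 0.79, median -0.37 with a mean of 0.79) and neutrophil genes (4 of 6 risen and 1 fallen, also adjusted over the list alone, adjusted p = 0.64) did not pass. The largest rises included Efemp1 (9.03 ± 0.55), Onecut1 (8.53 ± 0.38) and Fitm1 (8.48 ± 0.31), besides Mup7, a member of a family of near-identical copies. Sst, Depdc1b and Map3k9 had 0 counts in the day 20 libraries and were at least 109-fold, 58.2-fold and 50.7-fold higher in those labelled day 0.

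Day 20 against day 10 gave 5150 risen and 6720 fallen genes of 16694, of which 3769 and 5341 changed at least 2-fold, with a median of -0.21 over all genes. The difference between tissues and that in sex chromosome transcripts apply here as well. All 26 hepatocyte secreted protein genes rose (median 6.44, adjusted p = 3.3e-20, and adjusted p = 0.14 with an estimated correlation), and all 23 mitosis genes fell (median -5.46, adjusted p = 4.8e-24), in both cases also adjusted over the list alone. Hamp was at 805 ± 2.6 against 4.06 ± 2 CPM (SD, n = 3). Immediate early and heat shock genes fell, 17 of 18 with 0 risen, also adjusted over the list alone (adjusted p = 2.8e-12, and adjusted p = 0.088 with an estimated correlation), with Fos at 4.83 ± 0.38 against 617 ± 85 CPM. With an estimated correlation, 7 lists held, namely mitosis, amino acid and urea cycle (29 of 31 risen, 1 fallen), PPAR-alpha targets (28 of 30 risen), lipogenesis (19 of 21 risen), cholangiocyte (9 of 13 fallen, 2 risen), iron and BMP (11 of 16 risen, 3 fallen) and Wnt targets (15 of 21 fallen, 3 risen), each with adjusted p = 0.047. Their counts were the same adjusted over each list alone.

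Other lists passed with the preset correlation and not with an estimated one, while fry called all 27 that passed with the preset. For those described here that passed, the counts were the same adjusted over each list alone. All 31 complement and coagulation genes rose (median 6.40, adjusted p = 7.4e-24, and adjusted p = 0.097 with an estimated correlation). All 31 cytochrome P450 genes rose (median 6.51, adjusted p = 2.7e-22, and adjusted p = 0.088 with an estimated correlation). All 20 male-biased liver genes rose (median 6.72, adjusted p = 4.9e-18, and adjusted p = 0.088 with an estimated correlation). Bile acid genes rose (23 of 24, with 1 fallen; adjusted p = 2.6e-18, and adjusted p = 0.088 with an estimated correlation). Gluconeogenesis genes rose (11 of 14, with 0 fallen; adjusted p = 5.1e-10, and adjusted p = 0.085 with an estimated correlation). S phase genes fell (22 of 24, with 2 risen; median -3.54, adjusted p = 2.5e-14, and adjusted p = 0.091 with an estimated correlation). Acute phase genes rose (23 of 33, with 5 fallen; adjusted p = 1.9e-07, and adjusted p = 0.25 with an estimated correlation). Endothelial genes rose (19 of 20, with 0 fallen; adjusted p = 4.5e-08, and adjusted p = 0.15 with an estimated correlation). Fibroblast genes rose (16 of 20, with 0 fallen; adjusted p = 0.00033, and adjusted p = 0.28 with an estimated correlation). Macrophage genes rose (14 of 19, with 3 fallen; adjusted p = 0.0036, and adjusted p = 0.25 with an estimated correlation). Erythroid genes rose (6 of 9, with 3 fallen; adjusted p = 0.021, and adjusted p = 0.31 with an estimated correlation). T and NK cell genes (5 of 12 risen, 4 adjusted over the list alone, adjusted p = 0.51), B and plasma cell genes (1 of 7 risen, 3 fallen, also adjusted over the list alone, adjusted p = 0.91) and neutrophil genes (2 of 6 risen, 1 fallen, also adjusted over the list alone, adjusted p = 0.71) did not pass. Sst and Map3k9, at 0 counts on day 20, were at least 76.4-fold and 82.9-fold higher in the libraries labelled day 10.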

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

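The difference of the hepatectomy effect between crypts and IEC was tested directly, and each result below differed between the fractions by that test; the tests of liver content by marker level and by a fixed share, of library series, of thinning weighted by the TMM factors, and of the clock genes were chosen only after the result was seen. Of all genes, 3499 differed. Among the lists, medians of the difference (crypts minus IEC) were 0.256 for stem cell, 0.178 for Wnt target, 0.172 for S phase, 0.278 for mitosis and 0.287 for lipogenesis genes. They were -0.734 for Paneth, -1.02 for goblet and -0.469 for tuft cell genes, -0.316 for PPAR-alpha targets, -0.602 for MHC class II and -0.509 for immediate early and heat shock genes. For T and NK, B and plasma, and erythroid genes they were -1.11, -0.896 and -1.47. With an estimated correlation the goblet, mitosis, erythroid, and T and NK lists held, and the other 10 had adjusted p = 0.11 or more. Of single genes, gastric-type Tff1 (3.67), Gkn2 (3.40) and Gkn1 (3.26) and also BC049987 (2.22) had the higher effects in crypts named by rule. Defa35 (-7.41), Erdr1 (-3.64), G0s2 (-3.50) and Stox2 (-3.33) had the lower ones. G0s2 had an unstable call, and Defa35 shares sequence with other defensins.

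The libraries labelled liver day 0 and day 10 hold intestinal transcripts. Liver tissue with intestinal RNA mixed in would need liver genes at a sizeable share of the day 20 level, but their median was at most 2.1% of it in any of the 6 libraries. Intestinal libraries under liver labels remain a candidate explanation, since the correlation with sham crypts exceeded that with day 20 by at least 0.218 in each library. The remaining hepatocyte transcripts may be a fixed share of hepatocyte RNA or reads, as the wider quartile range of the log2 ratio over hepatocyte genes was 0.549. Other liver cell types stood at other shares of the day 20 level, with Kupffer cell genes at 0.892 to 7.33% and endothelial genes at 0.629 to 4.63% per library against 0.471 to 1.83% for hepatocyte genes, so 1 share for whole liver tissue is not shown. No biological explanation was tested.

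Genes silent in gut epithelium have higher counts in the hepatectomy libraries. Deeper sequencing as the whole cause would close most of the gap in genes detected once libraries are thinned, but 79.2% or more of the gap stayed at equal total counts, which still differ in the share of rRNA-like counts. With totals weighted by the TMM factors, 92.1% or more stayed. A background spread over all silent genes remains a candidate for these higher counts. In 3 further families (keratin-associated proteins, taste receptors and trace amine receptors) the lowest ratio of hepatectomy over sham was 1.88. It came from 8 trace amine receptor genes in crypts, at 0.3 ± 0.2 against 0.16 ± 0.039 CPM of all counts (SD). These values are near 0 with overlapping spreads, and the families repeat the pattern without showing its cause. A separate library series cannot be told apart from the treatment, because 0 of the 4 groups hold libraries of both series as read from the running numbers of the libraries. No biological explanation was tested.

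Clock genes differ between sham and hepatectomy libraries in both fractions. The median absolute difference over all 16 clock genes tested, called or not, was at least 13.1 times the 99th percentile of silent genes. It was taken in CPM of all counts, where scaling between libraries also moves expressed genes. The ratio therefore cannot exclude the background of silent genes as a cause. Arntl, Npas2 and Nfil3 fell in both fractions, the direction opposite to that background. A shift of clock phase may explain the differences in clock genes, since the medians of the opposing arms differed by at least 1.08 on the log2 scale. However, Hlf (-1.43) and Per1 (-0.603), of the arm expected to rise, fell in crypts. Such a shift, if present, cannot be told apart from collection time tied to the treatment groups, because 0 groups have a collection time in their labels.

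For the pairs of days, too few splits of the 6 libraries exist (10) for a share under 0.05. The real split called 5525 genes for day 10 against day 0, 12002 for day 20 against day 0 and 11517 for day 20 against day 10 in fits of those days alone. In each case 1 split, the real one, gave as many, and the highest of the other splits gave 0 with edgeR at the adjusted threshold.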

How the results depend on the processing

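Fits without replicate 3 of day 10 in the groups compared alone, and lists with a library left out, were chosen after seeing the data. Applied to the libraries labelled liver, the intestinal lists, also chosen then, passed in 3, 6 and 7 of 11 cases for the pairs of days, and in 0, 1 and 1 with an estimated correlation. The gene counts stayed within 1.5 times with DESeq2, RLE, no filter and the replicate block, and the block gave 6585 genes in crypts and 6461 for day 10 against day 0. Correlations between libraries of different groups, after removing group means, were -0.051 to 0.042 and showed no pairing by replicate number. They were taken over all genes tested, where counting error also enters, so shared animals are not excluded. A log2 fold change of at least 1 left 1596 genes in crypts, 1431 in IEC, 711 for their difference, 1646 for crypts against IEC and 3479 for day 10 against day 0, since it asks for more. The stricter filter gave 3950 for day 10 against day 0, where 10740 genes were tested. Without the filter the median of all genes moved to 0.17 in crypts, 0.20 in IEC, 0.46 for day 10 against day 0, and -0.46 and -0.86 for day 20 against day 0 and day 10. With DESeq2 it was 0.22, 0.25, 0.71, -0.33 and -1.00. For the difference between fractions the stricter filter gave 1340 higher and 2117 lower. In the fit of day 0 and day 10 alone 2136 genes rose and 3389 fell, against 4129 and 3146 with day 20 in the fit, and this turn was also seen without replicate 1, 2 or 3 of day 0 (2323 and 3572, 2518 and 3265, 2681 and 3671).

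With an estimated correlation, lists called were 10 in crypts (of 16), 6 in IEC (of 15), 4 for the difference (of 14), 9 for crypts against IEC (of 14), 0 for day 10 and 0 for day 20 against day 0 (of 22 and 25; camera, 6 and 12 at an unadjusted p under 0.05, fry 18 and 30) and 7 for day 20 against day 10 (of 27). In crypts the goblet and enterocyte lists held, but with adjusted p = 0.016 and 0.006 in place of 5.1e-42 and 3.3e-73. Fry gave 27 in IEC and 26 for crypts against IEC. The cause was not tested.

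With a library left out, genes called ranged from 4991 to 7039 in crypts, 5324 to 7171 in IEC, 2349 to 3099 for their difference, 5184 to 7232 for crypts against IEC, and 5783 to 8580, 10845 to 12624 and 11479 to 12957 for the pairs of days. Lists ranged from 14 to 16, 14 to 16, 13 to 14, 14 to 15, 15 to 22, 25 to 25 and 27 to 28, with 15 without replicate 3 of day 10, where 6 rose and 9 fell against 15 and 7 with it, and 13 were shared. Serpinf1 ranged from 0.83 to 1.40 for day 10 against day 0, lowest without replicate 3 of day 10, and was 0.773 (adjusted p = 0.082, range over the alternatives 0.00023 to 0.082) without it in these groups alone. For day 20 it ranged from 7.70 to 7.97 against day 0 and 6.47 to 7.06 against day 10.

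Signs reversed for genes near 0 or at low counts. Pnpla2 in crypts was -0.0437 without the filter and -0.00746 to 0.012 with a library left out. Rpsa for day 10 against day 0 was -0.145 without the filter, -0.0384 in these groups alone and -0.263 to 0.213 with a library left out. With a library left out, Des in IEC ranged from -0.607 to 1.34, Synpo2 from -0.776 to 2.47 for the difference and from -2.54 to 0.698 for crypts against IEC, and Ppara for crypts against IEC from -0.142 to 0.0107. Of 8593 alternatives for 594 values of named genes, 8346 kept direction and call, 223 lost the call, 7 gained it and 17 reversed; the cause was not tested. Depth limits genes such as Serpinf1 in the intestine, at 0 to 4 counts.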

Other observations

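The lists of intestinal cell types were applied to the libraries labelled liver only after their content was seen. In the libraries labelled day 10 against day 0, 11 of 19 enteroendocrine genes fell and 0 rose, also adjusted over the list alone (median -1.09, adjusted p = 7.2e-08, and adjusted p = 0.14 with an estimated correlation). Of 12 tuft cell genes, 11 rose and 0 fell (12 adjusted over the list alone; median 1.80, adjusted p = 7.2e-08, and adjusted p = 0.14 with an estimated correlation). Of 25 enterocyte genes, 15 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0032, and adjusted p = 0.76 with an estimated correlation). Stem cell genes (3 of 18 risen, 5 fallen, adjusted p = 0.49), Paneth cell genes (3 of 15 risen, 2 fallen, adjusted p = 0.72) and goblet cell genes (3 of 17 risen, 5 fallen, adjusted p = 0.27) did not pass, with the same counts adjusted over each list alone. In the libraries labelled day 20 against day 0, 16 of 18 stem cell genes fell and 0 rose, also adjusted over the list alone (median -4.48, adjusted p = 7.5e-12), a call that held with an estimated correlation.

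The lists below were not described above for the comparison named. In crypts, interferon response genes (9 of 26 risen, 5 fallen, and 10 and 6 adjusted over the list alone, adjusted p = 0.99), antimicrobial genes (8 of 17 risen, 7 fallen, and 8 and 8 adjusted over the list alone, adjusted p = 0.058), NF-kB genes (4 of 14 risen, 3 fallen, adjusted p = 0.74), p53 targets (2 of 14 risen, 2 fallen, adjusted p = 0.74) and regenerative epithelium genes (5 of 17 risen, 3 fallen, adjusted p = 0.74) did not pass. The last 3 had the same counts adjusted over each list alone. In IEC, interferon response genes (7 of 26 risen, 3 fallen, adjusted p = 0.54), NF-kB genes (1 of 14 risen, 6 fallen, adjusted p = 0.10), unfolded protein response genes (5 of 16 risen, 11 fallen, adjusted p = 0.18), p53 targets (4 of 14 risen, 0 fallen, adjusted p = 0.48) and regenerative epithelium genes (6 of 17 risen, 3 fallen, adjusted p = 0.53) did not pass either, with the same counts adjusted over each list alone.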
